A study of Homo sapiens with 6 samples.

How the data were processed

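RNA sequencing libraries were made from MDA-MB-231 cells, a human breast cancer line, in 2 groups of 3. Per the labels' protocols, the cells were seeded for 24 h, kept without serum for 24 h and then given CTU at 10 µM or its solvent DMSO for 6 h. The libraries were prepared from total RNA with a stranded kit, per the labels' protocols. CTU is known here only by its abbreviation, and no structure or class is given for it. Groups and replicate numbers were taken from the sample titles.

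The authors deposited a table of whole-number read counts per gene symbol, with 55765 rows, of which 25233 had at least 1 count. Per the submitters' processing notes, bcl2fastq 2.17.1.14, TopHat2 2.0.14, StringTie 1.0.4, edgeR and the genome build hg19 were used. The notes give no role or order for these tools. The counter, its annotation, its use of strand and its treatment of reads that match several genes are not given in the sources used here. Reads of near-identical genes, of overlapping genes and of antisense partners therefore cannot be assigned with certainty. Library totals ranged from 14375326 to 15434355 counts. Among the counted rows, 4 carried names that occur more than once, symbols turned into dates, and were kept apart under separate names. Genomic positions are not given, because the annotation at hand is of another build than hg19.

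The authors also deposited a table of their own comparison, with log2 fold changes and p-values in 14951 rows. Per the file headers it also holds counts, and 3 of its count columns share the heading Treat1 and were not used. In this table neighbouring fields can run together, so values were read by their number format, and in 2 rows the p-values could not be read. An Ensembl identifier was missing in 76 rows. Identifiers were taken from this table, and symbols are those of the count table.

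From the deposited counts, edgeR 4.0.16 in R 4.3.3 was used with TMM scaling factors and its filter on low counts, which kept 14625 genes. The quasi-likelihood test compared CTU with DMSO over all 6 libraries with no further covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and counts were also made at a fold of at least 2. The standard error of a log2 fold change was taken as its size divided by the square root of the test's F value. Levels are TMM-scaled CPM, counts relative to library size, given as mean ± SD. The common biological coefficient of variation was 4.87%.

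Before the data were examined, 35 gene lists were fixed, including markers of other cell types and signs of RNA quality. Lists with at least 3 tested members, 33 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera asks whether a list's genes move more than other genes do, and its p-values were adjusted over the lists. Beside each list stand the members changed over all genes tested and the members changed when adjusted over the list alone. Genes to be named were set beforehand as well. They were the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 50 counts and no overlap between the groups, and up to 4 members of each list with the smallest p. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

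The edgeR and camera steps were tested on simulated counts for CTU against DMSO with 14508 genes. The test recovered 44.6% of 65 genes changed 1.2-fold, 75% of 64 genes changed 1.5-fold and 93.9% of 66 genes changed 2-fold. Of 153 calls, 14 fell on genes simulated without change. A list simulated as raised was called, with an adjusted p of 1.14e-33 from limma's camera, and 0 of 34 unchanged lists were. The genes were simulated independently of each other. This therefore does not show how often camera calls an unchanged list whose genes move together.

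Alternatives were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no filter or a mean of at least 50 counts in place of edgeR's filter, DESeq2 1.42.0 and limma voom in place of edgeR, the replicate number as a block, each library left out in turn, and a test against a fold of 1.5. For the lists they were an estimated correlation, fry, the block, DESeq2 size factors, no filter and each library left out. Fry's p tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. Member counts of lists under the other scalings were added after the data had been seen.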

Results

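The transcriptome of MDA-MB-231 cells, a line derived from a human breast tumour, was measured by RNA sequencing after 6 h with 10 µM CTU and compared with cells given DMSO alone. Each group held 3 libraries. Total counts were 14433322, 15434355 and 14697015 in the DMSO libraries and 14791819, 15344980 and 14375326 in the CTU libraries. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom between 2.48 and 3.72 over their pairs. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component of the 500 most variable genes held 85.1% of their variance and separated the groups. Mitochondrial transcripts took 5.09% to 5.63% of counts in the DMSO libraries and 5.28% to 5.54% in the CTU libraries.

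The comparison asked which transcripts differed after 6 h of CTU. Transcripts of chemokines, interleukins and ATF4 and CHOP targets were far higher with CTU, and those of cell-cycle and cholesterol-synthesis genes were moderately lower. CXCL2, a chemokine that attracts neutrophils, rose 41.6-fold, from 2.07 ± 0.238 to 86.2 ± 17.6 CPM, TMM-scaled counts relative to library size (SD, n = 3). CXCL8, listed as IL8, another chemokine of this kind, rose 23.9-fold, from 23.3 ± 0.297 to 559 ± 92.6 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 36.3-fold, and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose 26.2-fold. Of the falls, the sharpest by the naming rule was EGLN3, an oxygen-sensing prolyl hydroxylase, which fell from 5.12 ± 0.669 to 1.80 ± 0.441 CPM.

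The remaining large rises included further secreted signals. CXCL3 (ENSG00000163734), a close relative of CXCL2 (ENSG00000081041), had a log2 fold change of 5.16 ± 0.159 (SE). The interleukins IL1A (ENSG00000115008) and IL1B (ENSG00000125538) had log2 fold changes of 4.13 ± 0.148 and 3.85 ± 0.093. GDF15 (ENSG00000130513), a stress-induced cytokine, had 3.93 ± 0.181, and TNFSF15 (ENSG00000181634), a TNF-family ligand, had 3.75 ± 0.138. RGS16 (ENSG00000143333), a regulator of G-protein signalling, had 5.12 ± 0.361, from 0.373 ± 0.028 CPM with DMSO to 13.2 ± 5.02 with CTU (SD). Its fold thus rests on few reads with DMSO. CXCL2, ANGPTL4 (ENSG00000167772), PTGS2 (ENSG00000073756) and CXCL8 (ENSG00000169429) had 5.38 ± 0.170, 5.18 ± 0.171, 4.71 ± 0.123 and 4.58 ± 0.101. The adjusted p of edgeR for these genes lay between 3.45e-15 for CXCL8 and 4.08e-09 for RGS16. CXCL2 and CXCL3 are similar in sequence, and reads may have been split between them.

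Falls were smaller. EGLN3 (ENSG00000129521) had a log2 fold change of -1.51 ± 0.20 and an adjusted p of 1.01e-05 in edgeR. The protocadherin PCDH18 (ENSG00000189184) had -1.34 ± 0.184, the caveolae-associated SDPR (ENSG00000168497) -1.32 ± 0.086 and the cyclic AMP phosphodiesterase PDE4B (ENSG00000184588) -1.31 ± 0.146. The zinc-finger gene ZNF488 (ENSG00000165388), the growth factor BMP4 (ENSG00000125378), FAM111B (ENSG00000189057) and TMEM97 (ENSG00000109084), a sterol-responsive membrane protein, had -1.31 ± 0.161, -1.25 ± 0.083, -1.19 ± 0.094 and -1.17 ± 0.072. The mitochondrial tRNA genes MT-TP (ENSG00000210196) and MT-TI (ENSG00000210100) had -1.39 ± 0.169 and -1.18 ± 0.165. In edgeR the adjusted p of these 9 genes lay between 7.27e-10 for TMEM97 and 1.87e-05 for MT-TI.

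**Figure D1:**
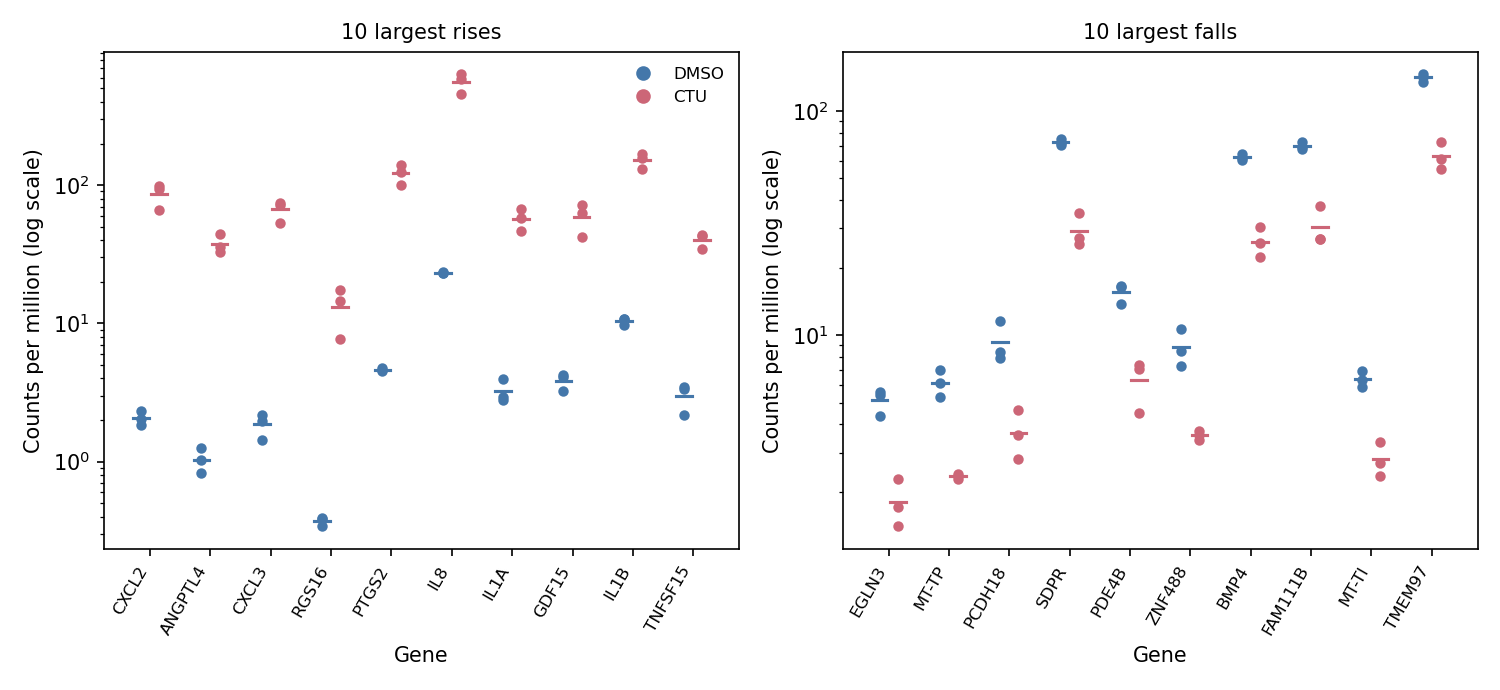
TMM-scaled CPM on a log axis for the 10 largest rises (left) and the 10 largest falls (right) under the naming rule. Each point is a library, with DMSO in blue and CTU in red, each bar is the mean of 3 libraries, and the groups lie apart for each gene, as the rule requires, from 2.07 to 86.2 CPM for CXCL2.

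In all, 5680 of 14625 genes changed in the edgeR test, 3106 higher and 2574 lower with CTU. The split depended on the scaling: 54.7% of the changed genes were higher with TMM factors, 36.4% with upper-quartile factors (2281 higher, 3979 lower) and 38.8% with library totals alone (2354 higher, 3720 lower). At a fold of at least 2, 410 genes changed, 310 higher and 100 lower, and 254 changed at a mean of at least 50 counts. The 100 became 152 without CTU replicate 1, 171 with no filter on low counts and 32 at that mean.

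Of the 33 lists tested, camera called 17, 11 of them higher and 6 lower with CTU. With a correlation estimated from the data 0 of the 17 were called by camera, and 3 had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 26 of the 33.

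Targets of ATF4 and CHOP, transcription factors of the integrated stress response, rose in 14 of 15 measured members, and in 14 when adjusted over the list alone. Their median log2 fold change was 1.99, with an adjusted p of 1.68e-12 from limma's camera and an adjusted p = 0.244 with an estimated correlation. DDIT4, an inhibitor of mTORC1 signalling, had 3.56 ± 0.098, and SESN2, a stress-inducible sestrin, had 2.99 ± 0.108. The glutathione-degrading enzyme CHAC1 and the asparagine synthetase ASNS had 2.58 ± 0.095 and 1.69 ± 0.067. Genes of amino acid synthesis and import rose in 17 of 17 members, and in 17 when adjusted over the list alone, with a median of 0.98 (limma's camera adjusted p 1.05e-12, adjusted p = 0.244 with an estimated correlation). CTH, an enzyme of cysteine synthesis, had 2.44 ± 0.083, the amino acid transporter SLC38A2 1.44 ± 0.050, the mitochondrial folate enzyme MTHFD2 1.40 ± 0.055, and the alanine aminotransferase GPT2 rose 2.29-fold. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, rose in 13 of 19 members, and in 14 when adjusted over the list alone, while 12 rose and 1 fell with upper-quartile factors. Their median was 0.51 (limma's camera adjusted p 3.57e-07, adjusted p = 0.244 with an estimated correlation), with GARS at 1.25 ± 0.047, SARS at 0.81 ± 0.043, MARS at 0.80 ± 0.047 and CARS at 0.79 ± 0.045.

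Chaperones and degradation factors of the endoplasmic reticulum rose in 18 of 25 members, and in 19 when adjusted over the list alone, while 15 rose and 1 fell with upper-quartile factors. The median was 0.30, with an adjusted p of 7.62e-06 from limma's camera and an adjusted p = 0.326 with an estimated correlation. HERPUD1 and DNAJB9, factors of ER-associated degradation, had 2.37 ± 0.099 and 2.05 ± 0.093. The chaperone HSPA5 (BiP) had 1.50 ± 0.093, and XBP1, a transcription factor of the unfolded protein response, had 1.45 ± 0.060. Cytosolic heat shock genes fell in 8 of 14 members, and in 10 when adjusted over the list alone. Their median was -0.13 (limma's camera adjusted p 0.00771, adjusted p = 0.367 with an estimated correlation). The co-chaperone BAG3 had -0.65 ± 0.045, and the chaperones HSPA8, DNAJA1 and HSP90AA1 had -0.51 ± 0.050, -0.35 ± 0.041 and -0.23 ± 0.048. Mitochondrial proteases and chaperones rose in 6 of 12 members, and in 6 when adjusted over the list alone, with a median of 0.13 (limma's camera adjusted p 0.0317, adjusted p = 0.368 with an estimated correlation, and 0.0873 without DMSO replicate 1). The protease LONP1 had 0.54 ± 0.056, the chaperone HSPA9 0.46 ± 0.050, its cofactor GRPEL1 0.30 ± 0.054 and the protease YME1L1 0.22 ± 0.041.

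Inflammatory cytokines and targets of NF-kB rose in 21 of 22 members, and in 21 when adjusted over the list alone, with a median of 1.77. The adjusted p of limma's camera was 1.41e-15, with an adjusted p = 0.244 with an estimated correlation. The members with the smallest p were CXCL8, IL1B, CXCL3 and CXCL2, given above. Immediate early genes, transcribed within minutes of a stimulus, rose in 21 of 22 members, and in 21 when adjusted over the list alone, with a median of 1.15 (limma's camera adjusted p 1.71e-10, adjusted p = 0.244 with an estimated correlation). The transcription factors EGR1, ATF3, KLF4 and MYC had 3.60 ± 0.143, 3.22 ± 0.141, 2.35 ± 0.106 and 1.69 ± 0.077. ATF3 also belongs to the list of ATF4 and CHOP targets. Feedback regulators of MAP kinase signalling rose in 13 of 15 members and fell in 1, and 14 rose and 1 fell when adjusted over the list alone. Their median was 0.84 (limma's camera adjusted p 1.45e-07, adjusted p = 0.244 with an estimated correlation). The phosphatases DUSP1 and DUSP5 had 3.01 ± 0.134 and 1.59 ± 0.051, the receptor kinase antagonist SPRY2 had 0.97 ± 0.056, and PHLDA1 rose 2.29-fold. SPRY1, a relative of SPRY2 that was chosen after its values were seen, was the member that fell, at -1.07.

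Genes of the extracellular matrix, migration and mesenchymal state rose in 18 of 25 members and fell in 1, and 20 rose and 1 fell when adjusted over the list alone. The median was 0.52 (limma's camera adjusted p 2.13e-07, adjusted p = 0.244 with an estimated correlation). The matrix metalloproteinases MMP3 and MMP1 had 3.05 ± 0.166 and 2.10 ± 0.080, the urokinase PLAU 1.22 ± 0.056 and the collagen-binding integrin ITGA2 1.18 ± 0.051. SNAI2, a repressor of epithelial genes that was chosen after its values were seen, was the member that fell, at -0.24. Ribosome biogenesis genes rose in 15 of 22 members, and 15 rose and 1 fell when adjusted over the list alone, while 12 rose and 2 fell with upper-quartile factors. Their median was 0.27 (limma's camera adjusted p 0.000129, adjusted p = 0.366 with an estimated correlation). RRP12, WDR43 and GNL3, nucleolar factors, had 0.69 ± 0.052, 0.69 ± 0.059 and 0.58 ± 0.044, and MYBBP1A had 0.37 ± 0.047. Ribosomal protein genes rose in 16 of 28 members, and in 17 when adjusted over the list alone, but in 3 with upper-quartile factors and 4 with library totals alone. Their median was 0.12 (limma's camera adjusted p 0.00156, adjusted p = 0.461 with an estimated correlation). RPL4, RPL3, RPL10A and RPL14 had 0.26 ± 0.040, 0.21 ± 0.042, 0.21 ± 0.043 and 0.19 ± 0.043, and reads of their many processed pseudogenes cannot be told apart with certainty. RPL14 did not pass with upper-quartile factors (0.11).

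Genes of cholesterol synthesis and uptake fell in 20 of 25 members, and in 21 when adjusted over the list alone, with a median of -0.50. The adjusted p of limma's camera was 3.15e-09, with an adjusted p = 0.244 with an estimated correlation. HMGCS1, MVK and IDI1, enzymes of the mevalonate pathway, had -0.90 ± 0.064, -0.77 ± 0.059 and -0.71 ± 0.052. Fatty acid synthesis genes fell in 10 of 15 members and rose in 3, and the counts were 10 and 3 when adjusted over the list alone, while 11 fell and 1 rose with upper-quartile factors or library totals alone. Their median was -0.25 (limma's camera adjusted p 0.0208, adjusted p = 0.541 with an estimated correlation). PNPLA3, a lipase-like protein of lipid droplets, had -0.94 ± 0.110, the elongase ELOVL6 -0.47 ± 0.051 and the phosphatidate phosphatase LPIN1 -0.35 ± 0.046. GPAM, an acyltransferase of glycerolipid synthesis, rose by 0.48 ± 0.064, and the acyl-CoA synthetase ACSL3 and the transcription factor SREBF1, each chosen after its values were seen, rose by 0.18 and 0.16. With upper-quartile factors ACSL3 (0.10) and SREBF1 (0.08) did not pass, nor with library totals alone (0.11 and 0.09). ACSL3 did not pass without CTU replicate 3 (0.14), and SREBF1 did not without DMSO replicate 1 (0.15) or 2 (0.11), without CTU replicate 2 (0.14) or 3 (0.13), at a mean of at least 50 counts, with DESeq2 size factors, or in DESeq2 or limma voom. Genes of G1/S and DNA replication fell in 20 of 22 members, and in 20 when adjusted over the list alone, with a median of -0.37 (limma's camera adjusted p 1.55e-10, adjusted p = 0.244 with an estimated correlation). The origin factor ORC1 had -0.87 ± 0.080, the cyclin CCNE2 -0.71 ± 0.051, and the helicase subunits MCM4 and MCM2 -0.55 ± 0.045 and -0.51 ± 0.051. Genes of G2/M and mitosis fell in 23 of 24 members, and in 23 when adjusted over the list alone, with a median of -0.41 (limma's camera adjusted p 5.32e-11, adjusted p = 0.326 with an estimated correlation). The kinesins KIF20A and KIF11 had -1.03 ± 0.062 and -0.53 ± 0.047, and the proliferation marker MKI67 and the mitotic kinase AURKA both had -0.57, with standard errors of 0.045 and 0.052. Nuclear-encoded subunits of the respiratory chain fell in 9 of 30 members, and in 7 when adjusted over the list alone, with a median of -0.07, and in 15 with upper-quartile factors and 14 with library totals alone. The adjusted p of limma's camera was 0.0328, with an adjusted p = 0.62 with an estimated correlation, 0.192 without DMSO replicate 2 and 0.0674 without CTU replicate 3. NDUFB3 and NDUFA2 of complex I had -0.45 ± 0.090 and -0.33 ± 0.081, UQCRFS1 of complex III -0.17 ± 0.050 and SDHA of complex II -0.17 ± 0.044.

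**Figure D2:**
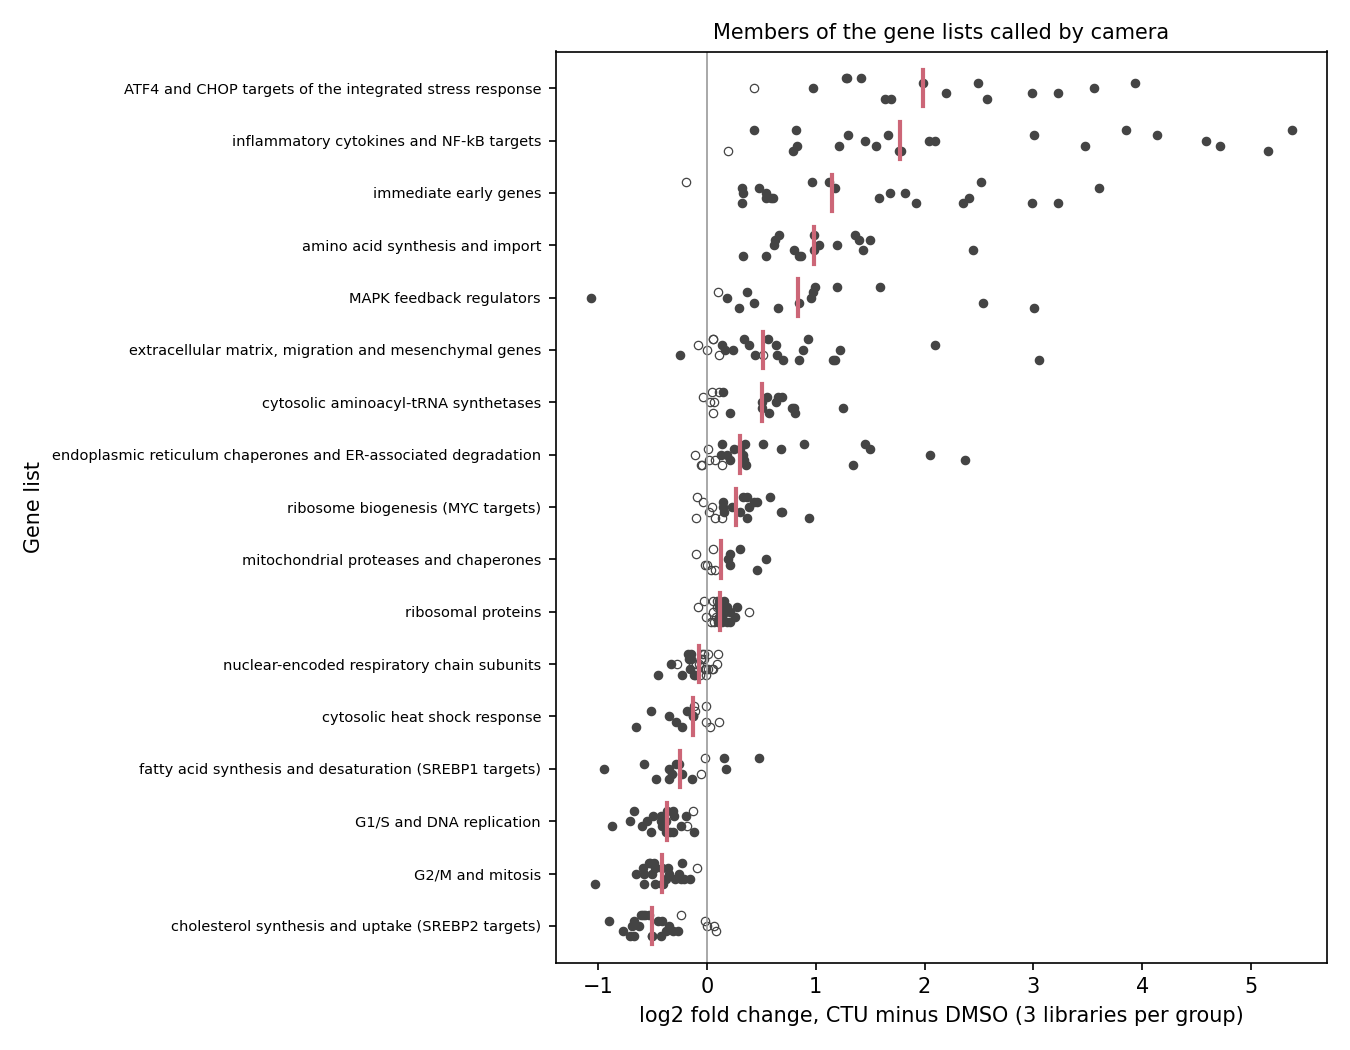
Log2 fold changes (CTU minus DMSO, horizontal axis) of the members of the 17 gene lists called by limma's camera, each circle a gene fitted over 3 libraries per group, filled where its adjusted p in edgeR is under 0.05, and the red bar the list's median. Medians run from -0.50 for cholesterol synthesis and uptake to 1.99 for ATF4 and CHOP targets, and 0 of the lists shown were called with an estimated correlation, where 3 had an unadjusted p under 0.05 in camera and fry called 26 of all lists.

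Camera did not call the remaining 16 lists tested, though some held genes that changed. Of fatty acid oxidation and PPAR targets, 7 of 20 rose and 4 fell (9 and 4 when adjusted over the list alone), with an adjusted p of 0.339 from limma's camera. Beside ANGPTL4, the lipid droplet protein PLIN2 rose by 1.77 ± 0.064, the pyruvate dehydrogenase kinase PDK4 by 1.68 ± 0.13 and the acyl-CoA dehydrogenase ACADVL by 0.39 ± 0.043. Of 6 LXR targets of sterol efflux 2 rose, and 2 when adjusted over the list alone, with an adjusted p of 0.75 from limma's camera. These were the cholesterol transporter ABCA1 at 2.10 ± 0.123 and the apolipoprotein APOE at 0.96 ± 0.286, with LPCAT3 at -0.13 and MYLIP at -0.17. The list's median was -0.07, while its mean was 0.43 and the test pointed up. APOE did not pass without DMSO replicate 2 (0.70), without CTU replicate 3 (0.91) or in DESeq2, and LPCAT3 passed with upper-quartile factors (-0.21). Of 12 prostaglandin genes 1 rose, PTGS2, and 1 fell, PTGES3 at -0.16 (1 and 1 when adjusted over the list alone), with PTGES2 at -0.20 and PTGES at 0.40 (limma's camera adjusted p 0.846). PTGES3 did not pass without DMSO replicate 1 (-0.15) or 2 (-0.11) or CTU replicate 3 (-0.11), PTGES2 passed without DMSO replicate 1 (-0.24) or CTU replicate 2 (-0.26), and PTGES passed without DMSO replicate 3 (0.49) or CTU replicate 1 (0.47). With upper-quartile factors 4 prostaglandin genes fell, PTGES2 (-0.28) among them, and PTGES2 also passed with library totals alone (-0.27) and at a mean of at least 50 counts (-0.21), and PTGES with no filter on low counts (0.39).

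Hypoxia and glycolysis genes went both ways, with 8 of 19 members higher and 6 lower (9 and 7 when adjusted over the list alone, limma's camera adjusted p 0.817), but 4 higher and 8 lower with upper-quartile factors. The angiogenic factor VEGFA rose by 1.36 ± 0.071 and the hexokinase HK2 by 1.02 ± 0.063, while the peptide hormone ADM had -0.85 ± 0.064 and EGLN3 fell as given above. Interferon-stimulated genes were higher in 4 and lower in 7 of 21 members (4 and 7 when adjusted over the list alone, limma's camera adjusted p 0.169). The antiviral genes OAS2, IFIT1 and OAS3 had -0.75 ± 0.144, -0.59 ± 0.083 and -0.57 ± 0.064, and the transcription factor IRF1 had 0.37 ± 0.063. Of the NRF2 antioxidant targets 6 of 21 rose and 7 fell (6 and 7 when adjusted over the list alone, limma's camera adjusted p 0.698), but 4 rose and 11 fell with upper-quartile factors. MAFG, a partner of NRF2, rose by 0.57 ± 0.047, and NQO1, PRDX1 and PGD had -0.27 ± 0.056, -0.29 ± 0.049 and -0.23 ± 0.043. This list's median was -0.07 and its mean 0.01, and the test pointed down. Aryl hydrocarbon receptor targets rose in 2 of 5 members, TIPARP at 0.92 ± 0.068 and CYP1B1 at 0.62 ± 0.116, and fell in 2, NQO1 and AHRR at -0.37 ± 0.13 (2 and 2 when adjusted over the list alone, limma's camera adjusted p 0.846). AHRR did not pass without DMSO replicate 2 (-0.33) or 3 (-0.37), without CTU replicate 3 (-0.26) or in DESeq2. Of the 4 metallothioneins measured, 0 were called by edgeR, over all genes and when adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (limma's camera adjusted p 0.912). MT2A had 0.25 ± 0.175, MT1X 0.50 ± 0.346, MT1E -0.04 ± 0.424 and MT1F -0.39 ± 0.601 (SE). MT2A and MT1X passed with no filter on low counts (0.24 and 0.49). Libraries of a group differed widely in these genes, with MT1E at 56.4 ± 33.7 CPM with DMSO and 55.2 ± 42.6 with CTU (SD). With such a spread a metallothionein that was not called may still have changed.

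Death and growth-arrest genes were mixed. Of p53 targets 7 of 17 rose and 2 fell (7 and 3 when adjusted over the list alone, limma's camera adjusted p 0.186), and 6 rose and 5 fell with upper-quartile factors. The growth-arrest gene GADD45A rose by 2.14 ± 0.099, the cell-cycle inhibitor CDKN1A by 1.29 ± 0.074, the TRAIL receptor TNFRSF10B by 1.23 ± 0.057 and the nuclease AEN by 0.92 ± 0.063. Apoptosis regulators rose in 10 of 20 members and fell in 5 (10 and 6 when adjusted over the list alone). Among them were the pro-apoptotic BBC3 at 1.76 ± 0.143 and PMAIP1 at 1.28 ± 0.053 and the anti-apoptotic MCL1 at 0.94 ± 0.052. The adjusted p of limma's camera was 0.0584 for this list, 0.0474 without CTU replicate 2 and 0.0114 with no filter on low counts. Autophagy and lysosome genes rose in 8 of 22 members (8 higher and 2 lower when adjusted over the list alone), with the kinase ULK1 at 1.33 ± 0.112, MAP1LC3B (LC3B) at 0.96 ± 0.059, WIPI1 at 0.65 ± 0.056 and the cargo receptor SQSTM1 at 0.61 ± 0.054, while 8 rose and 5 fell with upper-quartile factors. The adjusted p of limma's camera was 0.0523 for this list. It was 0.0451 without DMSO replicate 3, 0.0408 without CTU replicate 2, 0.0469 without CTU replicate 3 and 0.0147 with no filter on low counts.

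Of the 13 mitochondrially encoded mRNAs 1 rose and 3 fell (1 and 3 when adjusted over the list alone, limma's camera adjusted p 0.678). MT-ND6, the mRNA encoded on the light strand, fell by 0.82 ± 0.079, MT-CO1 fell by 0.21 ± 0.049 and MT-CO2 fell by 0.19 ± 0.056, while MT-ND1 rose by 0.16 ± 0.059, and 5 members fell with upper-quartile factors. MT-ND1 did not pass with upper-quartile factors or at a mean of at least 50 counts, nor without DMSO replicate 3 (0.07) or CTU replicate 1, 2 or 3 (0.17, 0.16 and 0.16), and MT-CO2 did not without DMSO replicate 1 (-0.15) or CTU replicate 2 (-0.14). The median was 0.03 and the mean -0.06, the test pointed down, and the median was -0.05 with upper-quartile factors. Of 8 replication-dependent histone genes 0 were called by edgeR, over all genes and when adjusted over the list alone, 1 had an unadjusted p under 0.05 and DESeq2 called 0 (limma's camera adjusted p 0.87, median 0.02, mean -0.03, test pointing down). HIST1H1C, HIST1H2BC, HIST1H2BK and HIST2H2BE had 0.26, -0.65, -0.15 and 0.34, and HIST1H1C passed without DMSO replicate 1 (0.35) and HIST2H2BE without DMSO replicate 3 (0.64). HIST1H2BK passed with upper-quartile factors (-0.23) and library totals alone (-0.22). Of 18 histone genes listed 8 were measured, and HIST1H2BC and HIST2H2BE lay low, at 0.94 and 2.44 CPM with DMSO. At such levels a gene that was not called may still have changed. Of 9 structural and host RNAs chosen as signs of RNA quality 4 rose, and 4 when adjusted over the list alone (limma's camera adjusted p 0.0909). These were the snoRNA hosts GAS5 and SNHG1 at 0.53 ± 0.052 and 0.41 ± 0.053 and the nuclear RNAs MALAT1 and NEAT1 at 0.35 ± 0.092 and 0.32 ± 0.118. NEAT1 did not pass without DMSO replicate 2 (0.14), without CTU replicate 2 (0.22) or 3 (0.32), with upper-quartile factors (0.24), at a mean of at least 50 counts (0.31) or in DESeq2.

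Most markers of other cell types did not pass the test. Of 9 luminal epithelial markers 2 rose, and 2 when adjusted over the list alone, XBP1 as given above and the oestrogen receptor ESR1 at 0.58 ± 0.176, with KRT8 at -0.10 and AGR2 at -0.42 (limma's camera adjusted p 0.518). ESR1 did not pass without DMSO replicate 1 (0.52), without CTU replicate 1 (0.53) or in DESeq2, and KRT8 passed with upper-quartile factors (-0.18). Of 5 fibroblast markers the collagen COL1A1 rose by 1.16 ± 0.136 and S100A4 had -0.39 ± 0.118 (1 rise and 1 fall when adjusted over the list alone, limma's camera adjusted p 0.518), with LUM at -0.22 and ACTA2 at -0.52. S100A4 did not pass in DESeq2, and LUM passed with upper-quartile factors (-0.30). COL1A1 also belongs to the matrix list. Too few leukocyte and endothelial markers were measured for a test. Of the 2 leukocyte markers CD8A and CSF1R, at -0.29 and -0.07, 0 passed in edgeR over all genes or when adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0. ESAM, an endothelial adhesion molecule, rose by 0.15 ± 0.047, 1 of 2 when adjusted over the list alone, and KDR had 0.10. ESAM did not pass with upper-quartile factors (0.07), without DMSO replicate 1 (0.13) or 2 (0.12) or without CTU replicate 2 (0.14) or 3 (0.15).

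The authors' deposited table gave 7149 genes with an adjusted p under 0.05, 2621 higher and 4528 lower with CTU, and 381 of them at least 2-fold. The authors' deposited table listed 5643 of the 5680 genes changed in the edgeR fit and called 5132 of these, and all 5132 had the same direction. Both comparisons rest on the same libraries, so this overlap is no independent support. At an adjusted p under 0.01 in edgeR, 3937 of 4025 genes were also called in the authors' deposited table. The authors' deposited table lists CXCL2 at a log2 fold change of 5.31 and EGLN3 at -1.58. Headings in the authors' deposited table differ from those of the count table: the column headed Cont2 held the counts of CTU replicate 1 and the one headed Cont3 those of DMSO replicate 2 in all 14929 rows compared.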

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

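The alternatives in this part were fixed before the data were examined, except the tests of list members under other scalings, which were chosen after the result was seen. The test against a fold of 1.5 gave 487 genes, 415 higher and 72 lower, fewer because it asks for more. Upper-quartile factors gave 3979 lower genes, where TMM gave 2574. A mean of at least 50 counts, which tests 11983 genes, gave 254 genes at a fold of at least 2 and 32 lower ones. With no filter, 25233 genes entered and 171 were at least 2-fold lower, and camera called apoptosis (adjusted p 0.0114) and autophagy (0.0147). Leaving out 1 library gave 106 to 152 genes at least 2-fold lower, and adjusted p of 0.0213 to 0.0873 for mitochondrial proteases, 0.0164 to 0.192 for respiratory chain subunits, 0.0474 to 0.0817 for apoptosis and 0.0408 to 0.0912 for autophagy. With an estimated correlation camera called 0 lists, 3 of the 17 at an unadjusted p under 0.05, where fry called 26. The adjusted p was 0.244 for ATF4 and CHOP targets, amino acid genes, aminoacyl-tRNA synthetases, cholesterol synthesis, NF-kB targets, immediate early genes, MAPK feedback, G1/S and matrix genes, 0.326 for ER chaperones and G2/M, 0.366 for ribosome biogenesis, 0.367 for heat shock genes, 0.368 for mitochondrial proteases, 0.461 for ribosomal proteins, 0.541 for fatty acid synthesis and 0.62 for respiratory chain subunits. Equal values come from the adjustment over the lists. The calls were lost because the estimated correlations of the 17, 0.106 to 0.669, lay above the preset 0.01, and a higher correlation raises camera's p. Each estimate rests on 4 residual degrees of freedom. With fry the adjusted p was 0.0736 for respiratory chain subunits, which it did not call, and 0.00356 for PPAR targets, 0.0131 for LXR targets, 0.0182 for hypoxia and for interferon-stimulated genes, 0.000237 for prostaglandin genes and for apoptosis, 0.00155 for p53 targets, 0.000548 for autophagy, 0.00137 for the RNA quality list and 0.017 for luminal markers, which camera did not call and fry does not compare with other genes. Where no reason is given, the cause was not tested. The replicate block gave 6098 changed genes, 415 of them at least 2-fold, and the deviations of libraries with the same number correlated at 0.061, 0.028 and 0.071, too weakly to pair them, though each library correlated best with its own number, a hint from the data. With the block MT1X (0.48), MT2A (0.26), HIST1H1C (0.26), PTGES (0.40) and PTGES2 (-0.20) passed, which did not without it. DESeq2 gave 4573 changed genes and limma voom 5652. For the 172 genes named in the text, no call reversed, though the sign changed in 9 of 2400 alternatives with no call in either setting; 24 calls were weaker, 19 stronger and 1325 the same over the other settings, and 37, 6 and 989 with a library left out. Of the members and medians of lists under other scalings, 61 moved and 344 did not. In simulated counts, with 65 genes changed 1.2-fold, 44.6% of these were recovered. Far fewer genes were changed in the simulation than were called in the data, so this share does not carry over to the data.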

Other observations

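In this part the tests of other splits and of decay factors were set before their results were seen, and the other tests and the gene families were chosen after the result was seen. Kruppel-like factors, zinc-finger regulators of transcription, rose in 11 of 13 measured members, and in 11 under each other scaling. Besides KLF4, KLF9 had a log2 fold change of 1.97 ± 0.168 (SE, n = 3 per group) and KLF7 1.28 ± 0.090. Of the EGF family ligands, which activate the EGF receptor family, 3 of 5 rose: EREG by 2.62 ± 0.073, HBEGF by 1.45 ± 0.067 and TGFA by 0.90 ± 0.103. BTC and EGF had -0.48 and -0.23 and did not pass. Of 8 frizzled genes, receptors for Wnt proteins, 4 fell and 1 rose, and 6 fell with upper-quartile factors or library totals. FZD4 had -0.81 ± 0.108, FZD1 -0.69 ± 0.081 and FZD8, the member that rose, 0.53 ± 0.086.

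Genes of the tubulin family, whose alpha and beta members build microtubules, fell in 9 of 13 measured members and rose in 1. With upper-quartile factors or library totals 11 fell. The 13 include the gamma, delta and epsilon tubulins TUBG1, TUBG2, TUBD1 and TUBE1. TUBB4B had -0.73 ± 0.050 and TUBA1A -0.74 ± 0.081, while TUBE1, of a divergent tubulin, had 1.30 ± 0.065. Of 20 actin and myosin cytoskeleton genes 8 fell and 3 rose, and 12 fell and 1 rose with upper-quartile factors or library totals. CNN2, ACTB and ACTG1 had -0.51 ± 0.048, -0.40 ± 0.046 and -0.32 ± 0.043. Reads of tubulin and actin genes can match their relatives and pseudogenes, and how such reads were counted is not given in the sources used here.

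With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Each other split puts libraries of both groups on both sides, so the CTU difference widens the spread within sides. Low counts of changed genes there were thus largely set by the design and do not exclude chance. For changed genes and for genes at least 2-fold changed the real values were 5680 and 410 and the highest of the other splits 0 in edgeR, whose other splits had 129 to 405 genes at an unadjusted p under 0.05, while DESeq2 called up to 2. For lists called by camera the real value was 17 and the other splits gave 7 to 15. In each case 1 split of the 10, the real one, gave a value as large.

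The authors' deposited table held more genes lower (4528) than higher (2621) with CTU, while TMM scaling gave more higher (3106) than lower (2574). Grouping by the table's headings is argued against: across genes, which are not independent replicates, the authors' log2 fold changes correlated at 0.741 with that grouping and at 0.99998 with the labelled one. A candidate explanation is scaling by library totals alone, since the authors' log2 fold changes minus a refit on totals had a median of -0.0038, against -0.0729 for those minus the TMM fit. Which scaling is nearer to the RNA per cell was not tested.

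Mitochondrial ribosomal RNA was higher with CTU, from 3959 ± 277 to 7460 ± 976 CPM for MT-RNR2 (SD, n = 3) and from 514 ± 29.6 to 735 ± 104 for MT-RNR1, while MT-ND6 and 6 of 7 measured mitochondrial tRNA genes fell. A rise of the whole mitochondrial genome is argued against by the median log2 fold change of 0.03 over its 13 mRNAs. Less complete removal of ribosomal RNA could raise the former, and stays open because nuclear ribosomal RNA genes held 119 counts in all over 521 entries, but it is argued against for the latter, whose summed level fell by 0.85 on the log2 scale, and by at least 0.67 in each CTU library. Lower transcription of the light strand alone may account for MT-ND6, but heavy-strand tRNAs had a log2 ratio of -1.2, at most -0.95 in any CTU library, from 414 and 172 counts, and this cannot be told apart from light-strand reads because the use of strand in counting is not given in the sources used here. No other biological explanation was tested, and an effect of CTU stays open.

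Host genes of small nucleolar RNAs rose in 12 of 16 measured members, with a median log2 fold change of 0.41, and ZFAS1, SNHG8 and GAS5 had 1.05 ± 0.075, 0.71 ± 0.076 and 0.53 ± 0.052. Of 9 RNAs chosen as signs of RNA quality 4 rose and 0 fell, the hosts GAS5 and SNHG1 together with MALAT1 and NEAT1. RNA quality as a cause was not tested. Scaling as the whole cause is argued against, since their median was 0.34 with library totals alone. Less nonsense-mediated decay, which degrades many of these transcripts, could raise them, but the mRNAs of 10 decay factors, which the pathway limits, had a median of 0.01, at the 42.2 percentile of 10000 random lists matched on expression. Members went both ways, with SMG1 higher by 0.24 and UPF2 and SMG6 lower, at -0.18 and -0.12. Levels of the factors' mRNAs do not measure decay itself, so they cannot decide the question. Less decay therefore stays open, as does an untested effect of CTU on transcription of the hosts. Neither UPF2 nor SMG6 passed in DESeq2, SMG6 did not pass with any library left out (-0.13 to -0.10), and UPF2 did not without DMSO replicate 1 or 2 or CTU replicate 2 (-0.17 to -0.14).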
